A study of Mus musculus with 12 samples.

How the data were processed

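Per the labels' protocols, frozen duodenal tissue was crushed, RNA was extracted with a column kit and stranded mRNA libraries were made. The deposited values are raw counts per Ensembl gene, per the file headers, whose column names end in the word raw, and they are whole numbers. Per the submitters' processing notes the genome build was GRCm38 and the tools listed were Trimmomatic, Cufflinks and Cuffdiff, with no versions and no order. The aligner, the counter, the annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on either strand and close paralogs hold uncertain counts. The batch tags stand in the file headers alone, and the labels name no batch. Genes with few reads are absent from the files, as the values show and no header or label states: in each infected group's file the counts of a gene over the group and uninfected tissue summed to at least 10 for genes present in both.

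The files held 21436 Ensembl IDs, of which 19857 stood in all 12 files and 1579 were left out of at least 1. Symbols came with the files for 21379 IDs and from GENCODE release M21 for 57, and gene positions, counted from 1, come from that release. IDs present in all 12 files were filtered with filterByExpr, which left 18194. A fit of FPKM values with limma had been planned, since the listed tools make FPKM; the files held counts, and the test written for that case before the data were examined was used. Counts were scaled with TMM factors and all 12 libraries were fitted in edgeR (version 4.0.16) with 6 group means and no further terms, so that all groups share 1 estimate of the spread (6 residual degrees of freedom, prior 3.13, biological coefficient of variation 23.4%). The quasi-likelihood F test was two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested in each comparison, and genes with adjusted p under 0.05 were called. CPM values use TMM-scaled library sizes, and fold changes are those fitted by edgeR.

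Before the data were examined, 39 gene lists were fixed from general knowledge of the tissue and infection, and each was tested at each day against uninfected tissue with camera of limma (version 3.58.1) with a preset correlation of 0.01, adjusted over 195 tests. Of these 118 passed, and 126 had a camera p under 0.05 before adjustment. With a correlation estimated from the data none passed camera, the lowest adjusted p being 0.30, and 30 had a camera p under 0.05 before adjustment. Fry, which asks whether a list moves on balance in 1 direction, was run beside it and passed for 21 of the tests. Day 6 against day 2 and day 14 against day 6 were tested the same way and adjusted apart. Several lists share members, such as Retnlb, Saa1 and Tap1, so that lists are not independent of each other. Members of a list were also adjusted over the list alone.

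The genes named were chosen by a rule written before the data were examined. For each day they are the 8 largest rises and 6 largest falls among called genes with both libraries beyond both uninfected libraries and at least 5 CPM. To these come up to 3 called members of each list past its test, and a short set of genes fixed in advance, such as Gbp2, Ifng and Retnlb. Gene models without a name and variable segments of antigen receptors were left out of the naming. Members of a list with the smallest p were added after the data were seen. Genes with 0 to 3 counts in uninfected tissue are given as levels. Their fitted fold changes are no measure of size and are given only where a sign turned under an alternative. On simulated counts with 200 changed genes the calling recovered 34, 38, 29, 31 and 39% of 2-fold changes and 85, 89, 85, 87 and 88% of 4-fold changes for days 1, 2, 4, 6 and 14. In that order, 1.65, 3.05, 6.56, 3.28 and 3.05% of calls were false. The changed genes were drawn from those with higher counts. Genes varied independently, and no difference in sex, tag or tissue piece was simulated. Apart from the changed genes, all groups were given the same means and the same spread. The shares thus differ between days through library size and random draw, not through the spread seen on each day. These shares hold for that setting alone, and a gene not called may still have changed. Between replicates of a group the spread exceeded sampling noise, with chi-square per degree of freedom from 26.6 in uninfected tissue to 246 at day 4. Other filters, scalings, DESeq2 (version 1.42.0), fits on fewer libraries and each library left out in turn were run as alternatives chosen before the data were examined. Terms for batch tag, Y-linked transcripts and Brunner gland score, alone or in pairs, the fit on libraries without a tag, the fit without the low-Muc6 libraries of days 4 and 6, and genes left out of a file taken as 0 were chosen after seeing the data.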

Results

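Whole duodenal tissue of C57BL/6 mice was profiled by RNA sequencing before and during infection with Hpb. In this field the abbreviation stands for Heligmosomoides polygyrus bakeri, an intestinal roundworm whose larvae enter the wall of the mouse duodenum and later return to the lumen as adults. The series holds 12 libraries in 6 groups of 2: uninfected tissue and tissue taken 1, 2, 4, 6 and 14 days after infection. The series title places the work on a type 1 immune and stromal response and disease tolerance, and each day was set against uninfected tissue to follow which genes changed and when. Gene counts per library summed to between 31313162 in day 2 replicate 1 and 72004517 in uninfected replicate 2. In all, 18194 genes had enough counts to be tested. Nothing in the labels says that the replicates came from separate mice, so p-values measure the spread between these libraries. Levels are in CPM, counts scaled to the size of the library, and gene positions are those of GRCm38.

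Several transcripts set single libraries apart from others of their group. Muc6, a mucin of Brunner's glands and stomach (ENSMUSG00000048191, chromosome 7, 141633456 to 141655319), stood at 2978 and 2799 CPM in uninfected tissue. It was at 13.1 in day 4 replicate 1, 4.43 in day 6 replicate 1 and 2.27 and 4.17 in the day 14 libraries. Exocrine pancreas genes took 1.52% of counts in day 2 replicate 2, 2.07% in day 4 replicate 1 and 0.729% and 2.8% at day 14, against 0.00859% and 0.00621% in uninfected tissue. Ddx3y, a Y-linked gene, was at 0.0529 CPM or less in both uninfected libraries and in replicate 1 of days 1, 4 and 6, where Xist was present. It was at 36.4 to 46 CPM in the other libraries, which include both of day 2 and both of day 14. At days 1, 4 and 6 Xist was at 156.7 to 211 CPM in replicate 1 and at 0.0505 to 0.55 in replicate 2. The replicates of these days thus cannot come from the same mouse, while for the other groups these transcripts leave that open. Nr1d1, a clock gene, was at 15.7 CPM in day 2 replicate 1, at 56.1 and 72.74 in the day 14 libraries and at 109.6 to 178 elsewhere. Dbp, another clock gene, was at 2.24 CPM in day 2 replicate 1 and at 9.849 and 19.59 at day 14. It was also low in day 6 replicate 1, at 22.26, and stood at 57.31 to 139.1 elsewhere. The count column headers carry a batch tag of 3 for day 2 replicate 1 and day 4 replicate 1, a tag of 2 for day 2 replicate 2 and both day 14 libraries, and none for the others. Days 1 and 6 can thus be set against uninfected tissue without crossing a tag and days 2 and 14 cannot. Within a day only the replicates of days 2 and 4 differ in tag, so a tag term rests on them. Those of day 4, the only pair with and without a tag, also differ in Muc6, pancreas share and Y-linked transcripts.

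**Figure D1:**
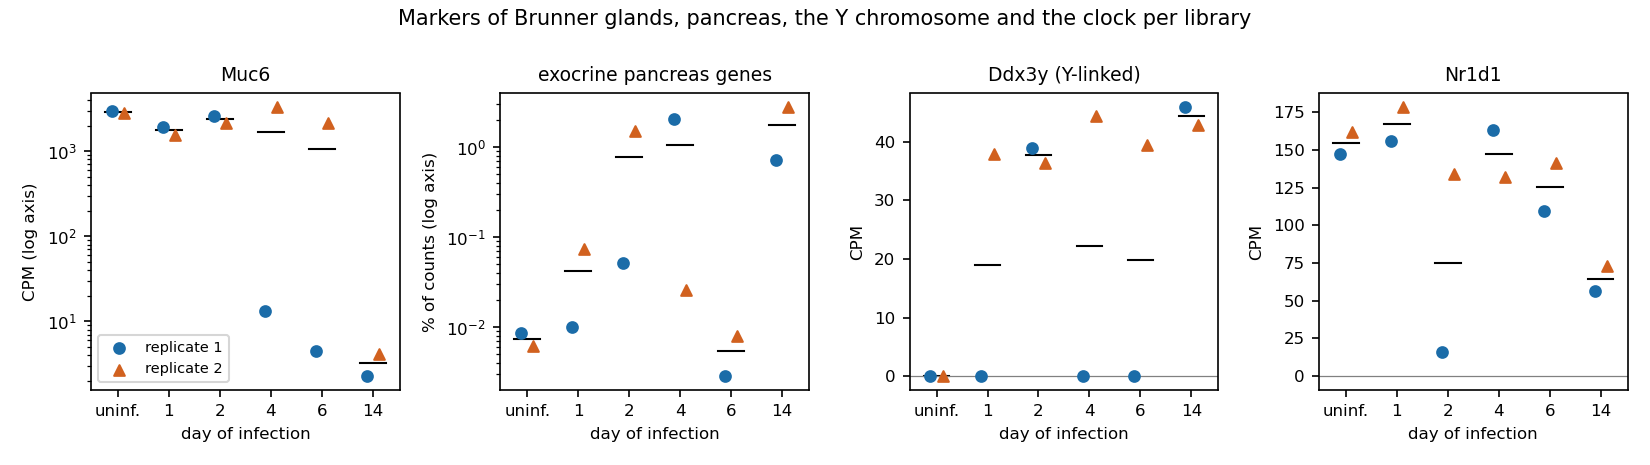
Level of Muc6 (CPM, log axis), share of counts from exocrine pancreas genes (percent, log axis), and levels of Ddx3y and Nr1d1 (CPM) in each of the 12 libraries, by day of infection, with circles for replicate 1, triangles for replicate 2 and bars for group means. Muc6 lay between 2.27 and 13.1 CPM in 4 libraries and at 1557 CPM or more in the other 8.

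At day 1 the genes that interferon-gamma induces stood higher than in uninfected tissue. The guanylate-binding protein gene Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008) measured 122 ± 74.1 CPM against 23.1 ± 1.7 (SD, n = 2 in each group). The chemokine gene Cxcl9, whose product draws T and NK cells, measured 37.2 ± 16.3 against 9.12 ± 1.75, and Cxcl10 18.8 ± 10.3 against 5.8 ± 2.05. All 35 measured members of the interferon-gamma response list lay above 0, with a median log2 fold change of 1.08. None passed over all genes tested, and 21 passed adjusted over the list alone. With Y-linked transcripts as a term 11 passed over all genes and 31 over the list alone. With Y-linked and Brunner gland terms these counts were 9 and 31. With the batch tag, the Brunner gland score, or batch tag and Y-linked terms, 0 passed over all genes. The list as a whole stood above other genes by camera (adjusted p = 4.34e-63; adjusted p = 0.30 with an estimated correlation). Fry, which tests the list against no change, did not pass (adjusted p = 0.114). In log2 CPM minus the mean of uninfected tissue the list's median was 1.46 in replicate 1 and 0.59 in replicate 2.

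Smaller shifts were found in other lists. The acute inflammatory cytokine list had a median of 0.71 with 5 of 20 members above the threshold adjusted over the list alone. The type 2 cytokine response list, the genes induced by IL-4 and IL-13, had a median of 0.60 with 2 of 20. In the latter list Retnlb, which codes for a goblet cell protein that acts against worms (ENSMUSG00000022650, chromosome 16, 48816856 to 48818892), measured 19.9 ± 6.02 CPM against 0.632 ± 0.0201, and Chil3, a gene of alternatively activated macrophages, 0.886 ± 0.637 against 0.0372 ± 0.012. MHC class II presentation had a median of 0.52 and the epithelial antimicrobial list 0.51, each with 1 member past the threshold adjusted over the list alone and none over all genes. These 4 lists passed camera (adjusted p = 2.08e-12, 2.26e-11, 6.27e-09 and 1.12e-08), with adjusted p = 0.30 to 0.314 with an estimated correlation. Xenobiotic metabolism genes, which detoxify dietary compounds, lay lower in 24 of 26 members, with 1 past the threshold adjusted over the list alone (median -0.34, camera adjusted p = 6.19e-09; adjusted p = 0.30 with an estimated correlation). Replicates 1 and 2 differed, with medians in log2 CPM minus the mean of uninfected tissue of 1.04 and 0.45 for the acute inflammatory list, 0.806 and 0.528 for the antimicrobial list and -0.518 and -0.217 for the xenobiotic list. The acute inflammatory and antimicrobial medians also moved by more than 1.5 times without uninfected replicate 1, and the xenobiotic median without uninfected replicate 2. Adipose markers were lower by camera (adjusted p = 0.00593; adjusted p = 0.56 with an estimated correlation) with no member called over all genes or over the list alone, and not without uninfected replicate 1 or day 1 replicate 2.

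No single gene passed at day 1 in edgeR's quasi-likelihood test over all genes (lowest adjusted p = 0.13). At an unadjusted p under 0.05 there were 588 genes, 319 higher and 269 lower. DESeq2 called 50, 47 of them higher. The fit on day 1 and uninfected libraries alone called 22. Gbp2 stood at 174 CPM in replicate 1 and 69.3 in replicate 2, and without replicate 2 the edgeR count was 4.

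Genes that rose at day 2 included those of the gasdermin C family, Retnlb and Pla2g4c. Gsdmc2 and Gsdmc4 are members of that family and lie on chromosome 15 (63824346 to 63845177 and 63891264 to 63912297). They rose to 151 ± 93.2 and 357 ± 190 CPM from 0.248 ± 0.167 and 0.709 ± 0.13 (SD, n = 2 in each group). Their neighbour Gsdmc3 rose to 27.1 ± 17.5 from 0.0444 ± 0.00189. These 3 genes are close paralogs, so that the split of reads between them is uncertain. Retnlb rose to 179 ± 28.7 CPM from 0.632 ± 0.0201 (edgeR adjusted p = 0.026), and the phospholipase gene Pla2g4c to 1510 ± 728 from 12.9 ± 4.24 (edgeR adjusted p = 0.0271). Duoxa2 and Duox2, an epithelial hydrogen peroxide source, rose to 260 ± 152 and 452 ± 235 CPM from 4.27 ± 0.314 and 18.9 ± 7.03. Cubn, a receptor for vitamin uptake (ENSMUSG00000026726, chromosome 2, 13276338 to 13491813), fell to 0.514 ± 0.0533 CPM from 40.5 ± 4.19, and the lactase gene Lct fell to 68.9 ± 11.6 from 757 ± 42.3.

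Immune lists rose as well. Of 35 interferon-gamma response genes 16 rose over all genes tested and 32 adjusted over the list alone, with a median log2 fold change of 1.44. The GTPase gene Iigp1 rose to 163 ± 1.11 CPM (edgeR adjusted p = 0.0279). Gbp2 rose to 163 ± 22 from 23.1 ± 1.7, Cxcl9 to 66.1 ± 11.1 from 9.12 ± 1.75 and Cxcl10 to 37.2 ± 10.3 from 5.8 ± 2.05. The camera adjusted p of this list was 2.67e-30, with adjusted p = 0.30 with an estimated correlation. Fry did not pass (adjusted p = 0.0523). Ifng itself was measured at 0.958 ± 0.0542 CPM against 0.162 ± 0.0349 (edgeR adjusted p = 0.0848). The type I interferon list did not pass (camera adjusted p = 0.172, median 0.22).

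In the acute inflammatory list 4 of 20 members rose, 12 adjusted over the list alone, among them the chemokine genes Cxcl5 (7.23 ± 0.0528 CPM from 0.132 ± 0.0571), Ccl7 and Ccl2 (6.28 ± 1.02 from 0.271 ± 0.124). In the type 2 list 6 of 20 rose, 10 adjusted over the list alone. Besides Retnlb, Chil3 rose to 2.3 ± 1.13 CPM from 0.0372 ± 0.012, Ccl8 20.7-fold and the arginase gene Arg1 4.3-fold. Neutrophil markers rose in 2 of 11 (5 adjusted over the list alone) and MHC class II genes in 3 of 10 (8 adjusted over the list alone), with Cd74 at 1480 ± 484 CPM against 501 ± 30.8. The camera adjusted p of these 4 lists was 6.86e-13, 8.56e-11, 2.31e-05 and 2.36e-08, and adjusted p = 0.30 to 0.32 with an estimated correlation. The mast cell protease gene Mcpt1, whose reads are hard to part from those of its paralog Mcpt2, rose to 41.5 ± 22 CPM from 3.28 ± 0.114, and Ly6a, a marker of epithelium under repair that interferon also induces, 7.24-fold.

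Epithelial lists changed at day 2 as well. Xenobiotic metabolism genes fell in 7 of 26 members, 22 adjusted over the list alone (median -1.10). The cytochrome gene Cyp3a25, which has close paralogs that make its counts uncertain, fell to 15.7 ± 6.91 CPM from 152 ± 26.5. Brush-border digestion genes fell in 3 of 25 (5 adjusted over the list alone) and stem cell markers in 3 of 16 (5), among them Axin2 and Ascl2. The stem cell receptor gene Lgr5 measured 1.78 ± 0.0509 CPM against 4.68 ± 0.403 (edgeR adjusted p = 0.0859). Proliferation genes rose in 9 of 32 members (12 adjusted over the list alone, median 0.53), such as Birc5, 1.98-fold. The camera adjusted p values of these 4 lists were 2.34e-20, 2.66e-07, 0.000115 and 5.22e-11, with adjusted p = 0.30 to 0.489 with an estimated correlation. Epithelial antimicrobial genes rose in 5 of 17 (10 adjusted over the list alone) and smooth muscle genes in 4 of 14 (6), with Actg2 rising to 416 ± 26.9 CPM from 83.6 ± 6.23. Both passed camera (adjusted p = 4.16e-08 and 5.17e-06), with adjusted p = 0.312 and 0.471 with an estimated correlation.

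Over all genes, edgeR called 613 at day 2, 363 higher and 250 lower, counting 16 rises and 26 falls among unnamed gene models and pseudogenes. The count was 1 without uninfected replicate 1, 0 without uninfected replicate 2, 0 without day 2 replicate 1, the library with shifted clock genes, and 20 without day 2 replicate 2. At an unadjusted p under 0.05 edgeR had 2196 genes without uninfected replicate 2 and 3070 without day 2 replicate 1, and DESeq2 on all libraries called 2011. Both day 2 libraries carry Y-linked transcripts and a batch tag. Replicate 2 carries pancreas transcripts, and 16 of 19 exocrine pancreas genes were higher adjusted over the list alone and none over all genes (camera adjusted p = 1.63e-08; adjusted p = 0.489 with an estimated correlation). The count was 186 with Y-linked transcripts as a term, with 78.5% of calls higher, and 234 with the batch tag, with 28.2%, in place of 59.2%. It was 46 with Y-linked transcripts and the Brunner gland score as terms together. In the fit with the batch tag the interferon-gamma median was 0.675, and the stem cell, smooth muscle and MHC class II lists no longer passed. That median was 2.21 with Y-linked transcripts and 1.93 with both terms.

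**Figure D2:**
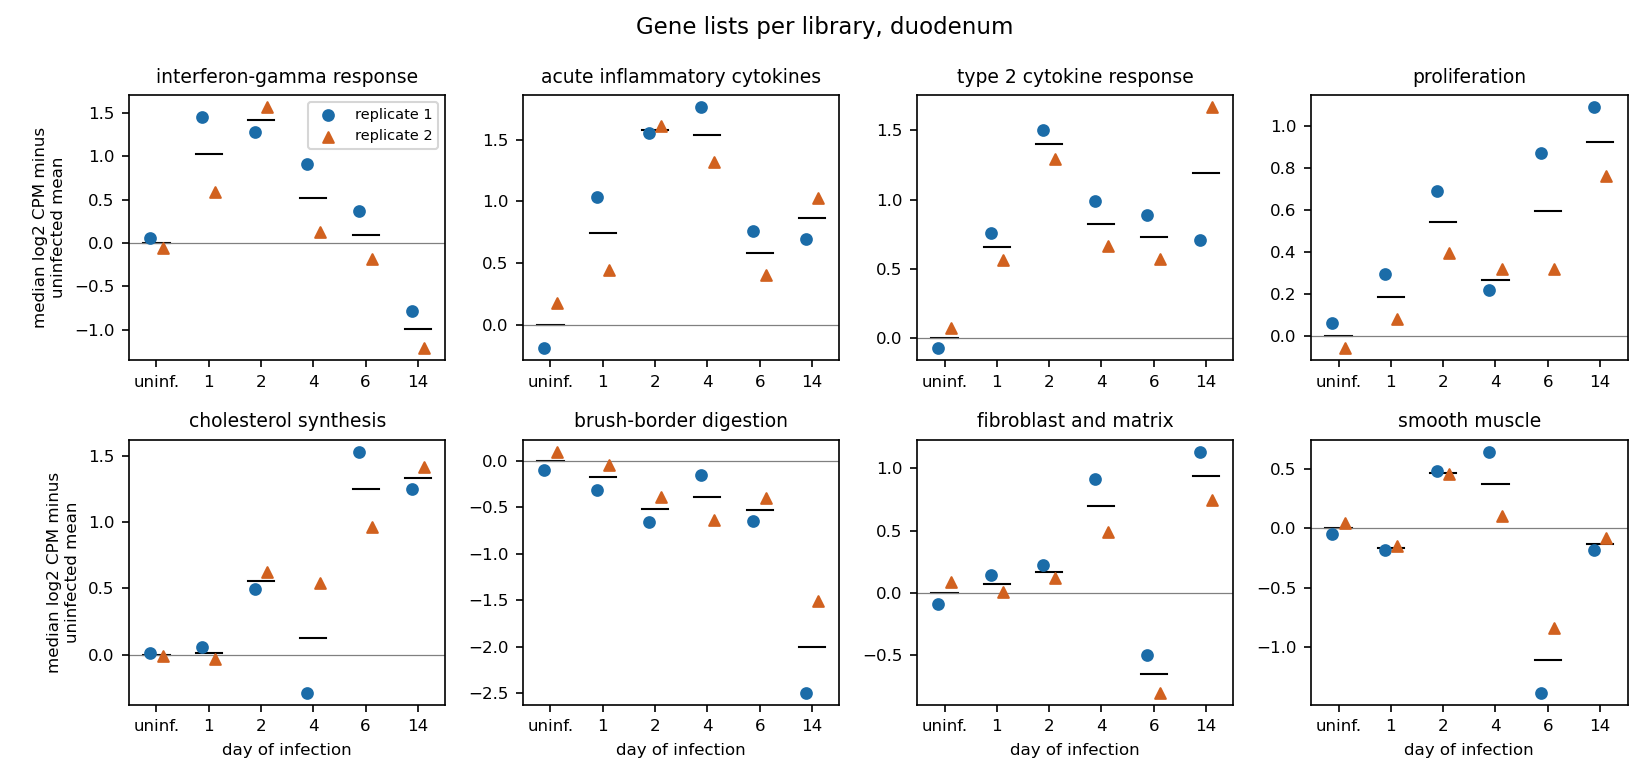
Median over the members of 8 gene lists of log2 CPM minus the mean of the uninfected libraries, in each of the 12 libraries by day of infection, with circles for replicate 1, triangles for replicate 2 and bars for group means. The interferon-gamma list lay above 0 in both libraries of days 1 and 2 and below it in both of day 14.

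At day 4 matrix and myeloid genes stood higher. The fibroblast and extracellular matrix list had 29 of 30 members above 0 (median log2 fold change 0.70), and monocyte and macrophage markers 17 of 18 (median 1.18), with 13 and 14 members past the threshold adjusted over the list alone and none over all genes. Acute inflammatory cytokines had a median of 1.63 (7 of 20 adjusted over the list alone) and neutrophil markers 2.04 (5 of 11 higher and 1 lower, adjusted over the list alone). Camera adjusted p values for these 4 lists were 1.45e-18, 6.96e-17, 1.72e-15 and 6.98e-06, with adjusted p = 0.30 for each with an estimated correlation. Type 2 response genes (median 0.94), MHC class II genes (median 0.94) and NK and cytotoxic markers (median 1.30) also passed camera at 1.12e-10, 1.96e-08 and 3.98e-11, with adjusted p = 0.30 to 0.344 with an estimated correlation. Replicate 1 stood higher than replicate 2 in all of these lists but neutrophil markers. In log2 CPM minus the mean of uninfected tissue, replicates 1 and 2 had medians of 1.63 and 0.62 for monocyte, 1.79 and 0.503 for NK, 1.31 and 0.479 for MHC class II and 0.912 and 0.485 for matrix genes. Neutrophil markers were at 1.283 and 1.565. Retnlb measured 7.37 ± 0.918 CPM against 0.632 ± 0.0201 (SD, n = 2 in each group) and Chil3 1.1 ± 0.206 against 0.0372 ± 0.012.

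The interferon-gamma list had a median of 0.56 at day 4, with no member past the threshold over all genes or adjusted over the list alone (camera adjusted p = 1.53e-07; adjusted p = 0.552 with an estimated correlation). Gbp2 measured 66.4 ± 22.6 CPM against 23.1 ± 1.7. Without day 4 replicate 1, or with the batch tag as a term, that list no longer passed, and neither did the NK list with the batch tag and Y-linked transcripts as terms together. With Y-linked transcripts alone as a term the interferon-gamma median was 0.883 (a fry p of 0.000692), with 11 of 35 members higher over all genes and 20 adjusted over the list alone. It was 0.96 with batch tag and Y-linked terms and 1.2 with Y-linked and Brunner gland terms. Lower medians came from the batch tag alone, at 0.121 (a fry p of 0.636), and the Brunner gland score alone, at 0.274 (a fry p of 0.291). In the libraries without a tag the median was 0.107. T cell markers lay above 0 in all 19 members (median 0.79, 2 adjusted over the list alone and none over all genes; camera adjusted p = 3.81e-07; adjusted p = 0.489 with an estimated correlation). They no longer passed without day 4 replicate 1 or with the batch tag as a term. In log2 CPM minus the mean of uninfected tissue, replicates 1 and 2 had medians of 0.913 and 0.13 for the interferon-gamma list, 1.06 and 0.252 for T cell markers and -0.146 and -0.64 for brush-border genes. Paneth cell markers lay lower in 15 of 18 members (median -0.87, 5 adjusted over the list alone) and brush-border genes in all 25 (median -0.42, 1 adjusted over the list alone). Camera gave adjusted p = 3.37e-08 and 1.53e-08, and adjusted p = 0.471 for both with an estimated correlation.

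No gene passed at day 4 in edgeR's test over all genes (lowest adjusted p = 0.0719), against 2021 at an unadjusted p under 0.05, 1302 of them higher, and 454 called by DESeq2. The day 4 libraries differed from each other in Muc6, pancreas genes, Y-linked genes and batch tag, and the count was 262 without replicate 2, 5 without replicate 1 and 145 with Y-linked transcripts as a term. With the low-Muc6 libraries of days 4 and 6 both left out it was 66, and in the libraries without a batch tag 2.

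At day 6 cholesterol synthesis and cell cycle genes rose while muscle, vessel and nerve genes fell. All 22 cholesterol synthesis genes lay above 0 with a median log2 fold change of 1.25. Of these 15 rose over all genes and 22 adjusted over the list alone. The pathway enzyme genes Mvd and Fdps rose to 90.7 ± 28 and 130 ± 27.1 CPM from 23.5 ± 0.489 and 39.5 ± 2.49 (SD, n = 2 in each group). Proliferation genes rose in 12 of 32 members (18 adjusted over the list alone), including Rrm2, 2.05-fold, and Aurka, 1.91-fold. Camera adjusted p values were 9.75e-20 and 2.46e-12, with adjusted p = 0.314 and 0.489 with an estimated correlation.

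Smooth muscle genes fell in 10 of 14 members (13 adjusted over the list alone, median -1.05), endothelial and lymphatic markers in 9 of 18 (12, median -0.88) and enteric neuron and glia markers in 5 of 13 (10, median -1.09). Synpo2 fell to 11.9 ± 2.77 CPM from 38.2 ± 4.24 and the endothelial receptor gene Tek to 1.95 ± 0.165 from 5.99 ± 0.257. The camera adjusted p was 1.08e-11, 1.53e-07 and 1.4e-06 for these 3 lists, with adjusted p = 0.312 to 0.47 with an estimated correlation. Fry gave adjusted p = 0.0352, 0.0358 and 0.0445. Replicates 1 and 2 had medians of -1.67 and -0.833 for neuron and glia markers in log2 CPM minus the mean of uninfected tissue. In the matrix list 9 of 30 members fell, such as Dpt, and 2 rose (13 and 2 adjusted over the list alone). The risers were the protease inhibitor gene Timp1, at 5.99 ± 2.87 CPM against 0.552 ± 0.133, and the protease gene Mmp3. The list's median was -0.63 (camera adjusted p = 0.000433; adjusted p = 0.496 with an estimated correlation), and without day 6 replicate 2 it no longer passed. Markers of adjoining tissue were lower too. Adipose markers fell in 1 of 10 members (3 adjusted over the list alone; camera adjusted p = 0.0056; adjusted p = 0.552 with an estimated correlation). The Brunner gland and stomach list had no member called over all genes or over the list alone (median -1.50, camera adjusted p = 0.0407; adjusted p = 0.659 with an estimated correlation). Its medians were -8.06 and -0.32 in replicates 1 and 2, and it no longer passed without day 6 replicate 1 or uninfected replicate 1.

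Type 2 genes rose in 6 of 20 members at day 6 (8 adjusted over the list alone). Arg1 rose to 14.8 ± 9.6 CPM from 1.28 ± 0.227 (edgeR adjusted p = 0.015), the eosinophil chemokine gene Ccl24 20.7-fold, Retnlb to 35.1 ± 21.7 CPM and Chil3 to 2.21 ± 1.6 from 0.0372 ± 0.012. Acute inflammatory cytokines rose in 4 of 20 (7 adjusted over the list alone), among them Ccl7. Stem cell markers fell in 6 of 16 (7 adjusted over the list alone), with Lgr5 at 1.64 ± 0.0599 CPM against 4.68 ± 0.403. Paneth cell markers fell in 5 of 18 (5), among them the alpha-defensin genes Defa21 and Defa22, whose near-identical copies make single values uncertain. Camera adjusted p values were 1.73e-05, 3.69e-05, 5.07e-05 and 3.62e-06, with adjusted p = 0.30 to 0.489 with an estimated correlation. The interferon-gamma list did not pass (median 0.15, camera adjusted p = 0.126), and Gbp2 measured 34.1 ± 7.85 CPM. That median was 0.426 with Y-linked transcripts as a term (a fry p of 0.0114; 3 members higher over all genes and 9 adjusted over the list alone). It was 0.423 with batch tag and Y-linked terms (a fry p of 0.0293), 0.518 with Y-linked and Brunner gland terms (a fry p of 0.0452) and -0.215 with the Brunner gland score alone (a fry p of 0.575). The gasdermin genes were higher, Gsdmc4 at 66.9 ± 38.3 CPM and Gsdmc2 at 34 ± 24.6, and Cubn fell to 1.89 ± 0.319.

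EdgeR called 2091 genes at day 6, 1028 higher and 1063 lower. Of these calls 49.2% were higher, 37.2% after scaling to totals without pancreas, immunoglobulin and mitochondrial genes and 64.7% after quantile normalization. Among the 942 calls with at least a 2-fold change 158 were higher and 784 lower. In the libraries without a batch tag, which hold both groups whole, the count was 2971. It was 0 without either uninfected library (4097 and 3338 genes at an unadjusted p under 0.05 in edgeR without replicates 1 and 2; DESeq2 on all libraries called 3449), 2 without day 6 replicate 1, the low-Muc6 library, and 2 in the fit on the 4 libraries of the comparison. With Y-linked transcripts and the Brunner gland score as terms together edgeR called 0, with 2381 at an unadjusted p under 0.05, against 3449 in DESeq2 without terms.

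At day 14 absorptive genes fell: 24 of 25 brush-border genes (25 adjusted over the list alone, median log2 fold change -1.85), 15 of 26 xenobiotic metabolism genes (17), 8 of 10 iron and calcium absorption genes (8) and 9 of 20 lipid absorption genes (11). Lct fell to 1.45 ± 0.599 CPM from 757 ± 42.3 (SD, n = 2 in each group), a log2 fold change of -9.05 ± 0.94 (SE; edgeR adjusted p = 0.00072). The calcium-binding protein gene S100g fell to 518 ± 148 from 4690 ± 41.9 and the cytochrome gene Cyp2b10 to 3.24 ± 1.34 from 167 ± 34.7. Camera adjusted p values for the 4 lists were 8.24e-18, 1.46e-11, 3.65e-05 and 6.47e-05, with adjusted p = 0.30 to 0.508 with an estimated correlation. Both day 14 libraries were low in Muc6, which fell to 3.22 ± 1.34 CPM from 2890 ± 127.

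Repair, matrix and growth genes rose. Matrix genes rose in 20 of 30 members (22 adjusted over the list alone), with Col1a1, a collagen chain, at 310 ± 71.5 CPM against 86.4 ± 7.97. Fetal-like epithelial repair genes rose in 11 of 21 (12), with Anxa1 at 175 ± 25.6 CPM against 12.7 ± 2.46, S100a6 at 1210 ± 155 against 122 ± 47.7 and Il1rn, the interleukin-1 receptor antagonist, at 89.3 ± 26.5 against 1.57 ± 0.334. The alarmin gene Il33 rose to 123 ± 6.53 CPM from 22.4 ± 4.92 (edgeR adjusted p = 0.00547). Proliferation genes rose in 27 of 32 (31 adjusted over the list alone) and cholesterol synthesis genes in 16 of 22 (17). The camera adjusted p was 4.33e-09, 1.12e-08, 4.9e-14 and 2.85e-09, with adjusted p = 0.30 to 0.489 with an estimated correlation.

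Interferon, T cell and NK cell genes fell at day 14. Type I interferon genes fell in 19 of 27 members (21 adjusted over the list alone), with Ifit1 at 17.6 ± 0.156 CPM against 147 ± 38.2. NK and cytotoxic markers fell in 10 of 17 (10), with the granzyme gene Gzmb at 5.31 ± 1.71 against 55.8 ± 0.712. MHC class I genes fell in 12 of 17 (13) and T cell markers in 10 of 19 (12), with Cd8a at 2.93 ± 0.64 against 21.5 ± 2.49. Camera adjusted p values were 7.13e-10, 2.85e-08, 4.6e-08 and 1.17e-06, with adjusted p = 0.47 to 0.496 with an estimated correlation. The interferon-gamma list fell in 13 of 35 members (16 adjusted over the list alone, median -0.89; camera adjusted p = 5.19e-07; adjusted p = 0.563 with an estimated correlation). With Y-linked transcripts as a term its median was -0.02 and it no longer passed, while with the batch tag as a term the median was -1.8. Type 2 genes rose in 9 of 20 (10 adjusted over the list alone) and mast cell markers in 5 of 10 (7). Chil3 measured 7.61 ± 2.69 CPM, Mcpt1 95.9 ± 98.9 from 3.28 ± 0.114 and Retnlb 86.6 ± 109 from 0.632 ± 0.0201. Retnlb was at 9.7 in replicate 1 and 164 in replicate 2. Camera gave adjusted p = 3.76e-05 and 0.0056, and adjusted p = 0.471 and 0.508 with an estimated correlation, and without day 14 replicate 2 the mast cell list no longer passed.

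Digestive enzyme genes of the exocrine pancreas were among those called higher at day 14, such as Cpa1 (965 ± 805 CPM from 0.00718 ± 0.0101), Cela2a and Try5, the last with close paralogs that make its counts uncertain. The chymotrypsinogen gene Ctrb1 (ENSMUSG00000031957, chromosome 8, 111686519 to 111691010) stood at 3160 ± 2770 CPM, at 3716 in day 4 replicate 1 and at 28 in day 4 replicate 2. EdgeR called 4501 genes, 2302 higher and 2199 lower. The share of rises was 51.1%, and 64.2% after scaling to totals without pancreas, immunoglobulin and mitochondrial genes, which moved the median log2 fold change of all genes to 0.129 (and to 0.105 at day 4). The count was 1702 and 1201 without uninfected replicates 1 and 2 and 2479 without day 14 replicate 1. Both day 14 libraries carry the same batch tag and Y-linked transcripts. With the batch tag as a term the count was 1083, 28.5% of them higher, with Y-linked transcripts 2697, and with the Brunner gland score 2611. With Y-linked transcripts and the Brunner gland score as terms together edgeR called 0, with 1858 at an unadjusted p under 0.05, against 5264 in DESeq2 without terms.

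**Figure D3:**
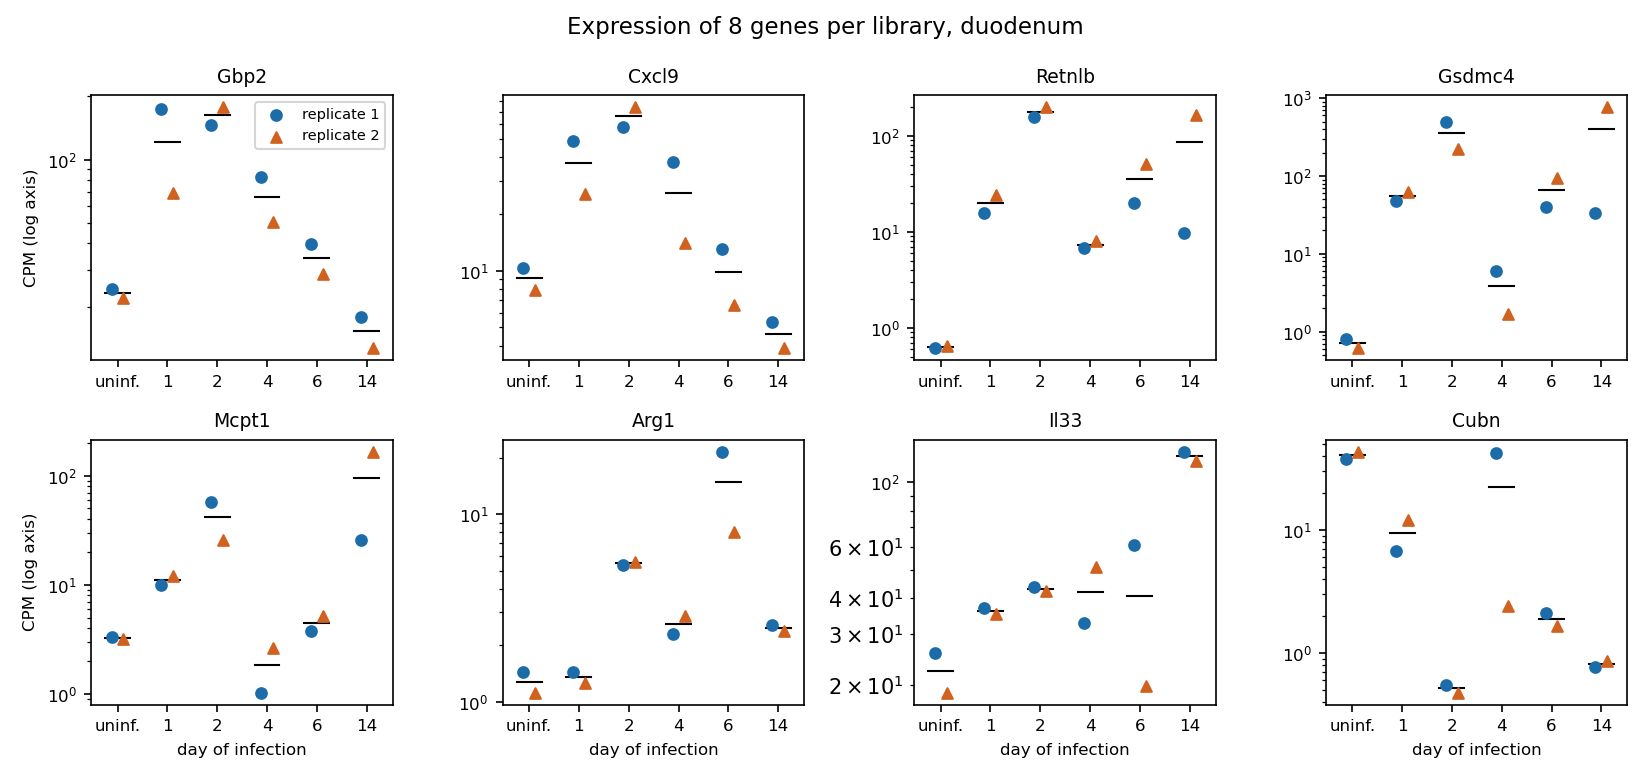
CPM on a log axis of Gbp2, Cxcl9, Retnlb, Gsdmc4, Mcpt1, Arg1, Il33 and Cubn in each of the 12 libraries by day of infection, with circles for replicate 1, triangles for replicate 2 and bars for group means. Gbp2 reached 147 and 178 CPM at day 2, and Il33 128 and 118 at day 14.

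Day 6 was set against day 2 to compare an early with a later phase. Smooth muscle genes fell between these days in 11 of 14 members (13 adjusted over the list alone, median -1.85), and interferon-gamma genes in 3 of 35 (30 adjusted over the list alone, median -1.49). Gbp2 went from 163 ± 22 to 34.1 ± 7.85 CPM (edgeR adjusted p = 0.0405), Cxcl9 from 66.1 ± 11.1 to 9.83 ± 4.61 (edgeR adjusted p = 0.043) and Ly6a from 144 ± 47.9 to 33.5 ± 12.3 (edgeR adjusted p = 0.0414). MHC class II and matrix genes fell in 2 of 10 and 4 of 30 (8 and 17 adjusted over the list alone). Camera adjusted p values for the 4 lists were 3.7e-36, 5.82e-23, 2.83e-10 and 2.47e-12, with adjusted p = 0.101 to 0.307 with an estimated correlation. Retnlb measured 35.1 ± 21.7 CPM at day 6 against 179 ± 28.7 at day 2 (edgeR adjusted p = 0.20). EdgeR called 247 genes, 53 higher and 194 lower at day 6. The count was 5 and 41 without day 2 replicates 1 and 2, and 0 and 553 without day 6 replicates 1 and 2. Without day 6 replicate 1 edgeR had 2265 genes at an unadjusted p under 0.05, and DESeq2 on all libraries called 1590. The day 2 libraries carry batch tags and the day 6 libraries none. With the tag as a term 47 genes were called, 72.3% of them higher in place of 21.5%, and the MHC class II list no longer passed. The interferon-gamma median was -0.576 in that fit, with a fry p of 0.435 against 0.00838 without the term. It was -1.89 with Y-linked transcripts as a term (a fry p of 8.44e-05) and -1.72 with both terms (a fry p of 0.0108).

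Day 14 was set against day 6 to compare the phase in which larvae lie in the gut wall with a later one. Matrix genes rose in 24 of 30 members (24 adjusted over the list alone), fetal-like repair genes in 14 of 21 (15), endothelial markers in 13 of 18 (13) and smooth muscle genes in 10 of 14 (12). Camera gave adjusted p = 5.52e-21, 1.21e-11, 4e-08 and 1.37e-06 and adjusted p = 0.101 to 0.351 with an estimated correlation. Interferon-gamma genes fell in 14 of 35 (22 adjusted over the list alone), MHC class I genes in 11 of 17 (14), NK and cytotoxic markers in 6 of 17 (11) and brush-border genes in 12 of 25 (15). Camera gave adjusted p = 7.16e-12, 1.8e-10, 7.06e-08 and 3.15e-11 and adjusted p = 0.341 to 0.375 with an estimated correlation. Arg1 fell from 14.8 ± 9.6 to 2.48 ± 0.136 CPM (edgeR adjusted p = 0.00455). Mcpt1 rose from 4.49 ± 1.01 to 95.9 ± 98.9 (edgeR adjusted p = 0.00868), Lgr5 from 1.64 ± 0.0599 to 6.12 ± 3.43 (edgeR adjusted p = 0.0139) and Il33 from 40.5 ± 29.1 to 123 ± 6.53 (edgeR adjusted p = 0.0323). EdgeR called 3298 genes, 1669 higher and 1629 lower at day 14. The share of rises was 50.6%, and 69.5% after that scaling, with the median of all genes at 0.184. The count was 1797 and 1927 without day 6 replicates 1 and 2 and 1256 without day 14 replicate 1. With the batch tag as a term it was 525, 32% of them higher, and the endothelial and smooth muscle lists no longer passed. The interferon-gamma median, -1.15 without terms, was -2.13 with the batch tag, -0.705 with Y-linked transcripts and -1.32 with the Brunner gland score. It was -0.816 with batch tag and Y-linked terms and -0.585 with Y-linked and Brunner gland terms.

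Tested over all 5 days together, 4576 genes differed from uninfected tissue on at least 1 day by edgeR's test at the adjusted threshold of 0.05. Dclk1, a tuft cell gene, and Mki67, a marker of dividing cells, passed on no day. Dclk1 measured 13.9 ± 1.23 CPM in uninfected tissue and between 12.5 ± 5.38 at day 6 and 28.7 ± 8.94 at day 14 (SD, n = 2 in each group). Its lowest edgeR adjusted p over the days was 0.0843. Il4 and Il25 had too few counts to be tested. Il13 was left out of the day 4 files and not tested, with 2 and 0 counts in uninfected replicates 1 and 2, 26 and 11 at day 2 and 11 and 64 at day 14. The count of genes was 1528 and 1358 without uninfected replicates 1 and 2. It was 2298 and 2266 without those of day 1, 2738 and 2831 without those of day 2, 2770 without day 6 replicate 1 and 2623 without day 14 replicate 1. DESeq2 called 7619.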

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

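Differences between 2 infected days, tested directly, single out the following results. The tests of batch and of sex, those of the Brunner gland term, alone and with Y-linked transcripts, and that of pancreas transcripts by time point were chosen only after the results were seen. That of low-Muc6 libraries within days 4 and 6 and that of pancreas pieces were set before their results were seen. In edgeR's test at an adjusted p under 0.05, 247 genes differed between day 2 and day 6 and 3298 between day 6 and day 14. Past both camera and fry, lists lower at day 6 than at day 2 were smooth muscle (median log2 fold change -1.85), mast cell markers (-2.5), interferon-gamma response (-1.49), neutrophil markers (-1.36), MHC class II (-1.35), fetal-like repair (-1.07), enteric neuron and glia (-0.964), plasma cell and immunoglobulin constant genes (-0.952), matrix (-0.814) and endothelial markers (-0.484). Xenobiotic metabolism was higher (0.69). Lists higher at day 14 than at day 6 were mast cell markers (3.34), red blood cell genes (2.36), matrix (1.72), fetal-like repair (1.6), endothelial markers (1.02), smooth muscle (0.987), enteric neuron and glia (0.663) and stem cell markers (0.607). Lower were NK and cytotoxic markers (-1.72), brush-border genes (-1.12), iron and calcium absorption (-1.01), MHC class I (-0.951) and xenobiotic metabolism (-0.896). With 1 library of the compared days left out, the median moved by more than 1.5 times for neuron and glia markers (day 6 replicate 1 or 2), xenobiotic metabolism (day 6 replicate 2), neutrophil markers (day 6 replicate 2), stem cell markers (day 6 replicate 2, day 14 replicate 1) and mast cell markers (day 14 replicate 2). With an estimated correlation none of these lists passed camera, the lowest adjusted p being 0.101.

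Genes left out of at least 1 file were fitted only in an alternative that takes them as 0 there. Both libraries of a group lay above both uninfected libraries for 235 of 720 such genes at day 1, 369 of 620 at day 2, 489 of 778 at day 4, 393 of 664 at day 6 and 588 of 894 at day 14. The genes left out of an infected group's file had an uninfected total of at most 9, while presence in such a file beside uninfected tissue went with a total of at least 10 over the 4 libraries. Selection alone thus puts infected libraries above uninfected ones, and no share by chance can be set beside these counts, which show no signal by themselves. Prss3 and Cuzd1, expressed in pancreas, led at day 4, with Prss3 at 1661 and 7 counts in replicates 1 and 2 and none in uninfected tissue. The neutrophil gene S100a8 held 52 and 10 counts at day 6 and 0 in uninfected tissue.

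The interferon-gamma list stood higher at days 1 and 2, and batch and sex were weighed as technical or design explanations beside infection. At day 1 neither group carries a batch tag, so the list's median log2 fold change of 1.07 in the libraries without a tag (0.587 to 1.46 with any of the 4 libraries left out) rests on the same libraries and decides nothing on a batch that is not marked. With Y-linked transcripts as a term the smaller of the day 1 and day 2 medians was 1.43, with a fry p of 0.000114 at most. That term rests on days 1, 4 and 6, in which the library with Y-linked transcripts had the lower list median. Those medians were 0.5895 against 1.457, 0.1301 against 0.9133 and -0.1893 against 0.3691, in log2 CPM minus the mean of uninfected tissue. At days 4 and 6 the library with Xist was also low in Muc6, so the term does not part sex from tissue piece. At day 2 sex and infection cannot be told apart, since both libraries differ from both uninfected ones in Y-linked transcripts. At day 2 the tag as a term lowered the median to 0.675 (a fry p of 0.33), and with both terms it was 1.93 (a fry p of 0.00677, 23 of 35 members past the threshold adjusted over the list alone), so that the fits with the tag differ and at day 2 infection and batch cannot be told apart, since both libraries of that day carry tags that no uninfected library has. A response to infection at day 1 is a hypothesis that stays open beside unmarked differences such as age, cage or day of dissection.

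The 4501 genes called at day 14 were weighed against tissue pieces without Brunner glands, batch and sex. Within days 4 and 6 the low-Muc6 library minus the other gave these genes a median log2 difference, signed by their direction at day 14, of 0.00415 (-0.188 at day 4 and 0.199 at day 6), against a median size of 0.964 at day 14, but the 2 days differ in sign and in both the low-Muc6 library is the one with Xist, opposite to day 14, so that the bound set for this test decides nothing. With the Brunner gland score and Y-linked transcripts as terms together 0 genes (0%) kept their call and direction in edgeR (1858 at an unadjusted p under 0.05; DESeq2 without terms 5264), while the median signed log2 fold change of the called genes was 1.02, which leaves a piece without Brunner glands joined to sex open. With a single term 861 (19.1%) kept theirs at a median of 1.19 for the batch tag, 2364 (52.5%) at 1.00 for Y-linked transcripts and 2178 (48.4%) at 0.919 for the Brunner gland score. Why calls ended was not tested. Each term is estimated from replicates of the same day that differ in it, and among those tag, sex and Muc6 are partly tied. Day 4 alone holds a tagged and an untagged library, and there tag, sex, Muc6 and pancreas share (2.07% against 0.0255%) are wholly tied. The tag 3 effect rests on that pair, and the tag 2 effect on it and on the day 2 pair. These counts thus cannot exclude any of the 3 as the sole cause. Both day 14 libraries share a tag, Y-linked transcripts and low Muc6. Their Nr1d1, at 56.13 and 72.74 CPM, also lay below the 147.5 and 161.7 of uninfected tissue. A joint cause may thus account for the breadth, and infection stays open as a hypothesis.

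Pancreas transcripts were abundant in day 2 replicate 2, day 4 replicate 1 and both day 14 libraries. Their share differed 29.5-fold between the day 2 replicates and 81.2-fold between those of day 4, which argues against the time point as the cause. In the 4 libraries with a share over 0.5% the 18 acinar genes kept 1 ratio to each other, with an SD of the log2 ratio between 0.111 and 0.325 over pairs of libraries, and the islet genes Ins1 and Ins2 were counted in all 4. Ins2 was at 1.32, 40.8, 12.6 and 7.67 CPM, at 0 in day 2 replicate 1 and day 4 replicate 2, and left out of the files of uninfected tissue and days 1 and 6. Pieces of pancreas taken along with the duodenum are a candidate source, and no biological explanation other than the time point was tested.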

How the results depend on the processing

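The alternatives with terms for batch tag, Y-linked transcripts or Brunner gland score, alone or in pairs, with libraries without a tag, with the low-Muc6 libraries of days 4 and 6 left out, or with left-out genes as 0 were chosen after seeing the data; all others before. Counts of called genes stayed within 1.5 times with no filter, DESeq2 size factors, totals without pancreas, immunoglobulin and mitochondrial genes, robust estimation and left-out genes as 0. Where a count moved by more than 1.5 times the cause was not tested, except that fewer libraries or more terms leave fewer degrees of freedom and a fold minimum removes small changes. The stricter filter called 1368 genes at day 6 in place of 2091, and quantile normalization 57 for day 6 against day 2 in place of 247. DESeq2 called 50 at day 1, 2011 at day 2, 454 at day 4, 3449 at day 6, 1590 for day 6 against day 2 and 7619 over any day. Fits on the 4 libraries of a comparison called 22 at day 1, 2663 at day 2, 2 at day 6, 0 for day 6 against day 2 (edgeR, 3162 at an unadjusted p under 0.05) and 911 for day 14 against day 6. Without the day 2 libraries 1255 genes were called at day 6. With at least a 2-fold change 288 genes were called at day 2 (58% higher), 942 at day 6 (16.8%), 2136 at day 14 (41.7%) and 1793 for day 14 against day 6 (63.5%). With the batch tag as a term 234 genes were called at day 2, 1 at day 4, 1083 at day 14, 47 for day 6 against day 2, 525 for day 14 against day 6 and 1041 over any day. With Y-linked transcripts 13 genes were called at day 1, 186 at day 2, 145 at day 4, 1224 at day 6, 2697 at day 14 and 2656 over any day. With both terms 86 genes were called at day 2, 5 at day 4, 756 at day 14, 4 for day 6 against day 2, 386 for day 14 against day 6 and 983 over any day. With the Brunner gland score 969 genes were called at day 6 and 2611 at day 14. With that score and Y-linked transcripts together 15 genes were called at day 1, 46 at day 2, 134 for day 6 against day 2, 495 for day 14 against day 6 and 485 over any day, and edgeR called 0 at days 6 and 14 (2381 and 1858 at an unadjusted p under 0.05; DESeq2 without terms 3449 and 5264). In the libraries without a tag 2 genes were called at day 4. Without the low-Muc6 libraries 1380 genes were called at day 2, 66 at day 4, 52 at day 6 and 41 for day 6 against day 2.

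With each library left out in turn, where a group of 1 is assumed to vary like the others, the counts ranged from 0 to 4 at day 1, 0 to 20 at day 2, 0 to 262 at day 4, 0 to 2608 at day 6 and 1201 to 3735 at day 14. They ranged from 0 to 553 for day 6 against day 2, 1256 to 3620 for day 14 against day 6, 1358 to 5561 over any day and 110 to 122 for the list tests. With an estimated correlation 0 list tests passed camera in place of 118. Before adjustment 30 had a camera p under 0.05 with that correlation and 126 at the preset, and DESeq2 has no such test. For the other alternatives run the count of list tests stayed within 1.5 times. The 276 fold changes of named genes were recomputed under the alternatives, which gave 6060 values: 4662 kept direction and side of the threshold, 1303 lost their call, 74 gained one and 21 reversed. Retnlb reversed for day 14 against day 6 without day 14 replicate 2 (log2 fold change -1.83, and up to 2.2 without another library). With batch tag and Y-linked terms together, day 14 log2 fold changes reversed for Cpa1 (-11.1), Cela2a (-12), Try5 (-11.8), Cel (-14.8), Pnlip (-14.9), Prss2 (-13.2), Ctrb1 (-12.8), Try4 (-17.2) and Hpgds (-0.0403). The tag term rests on replicates 1 and 2 of days 2 and 4, whose pancreas shares were 0.0516% and 1.52% at day 2 and 2.07% and 0.0255% at day 4. The reversed values of the pancreas genes are thus no measure of a fall at day 14. Why Hpgds reversed was not tested. With Y-linked and Brunner gland terms together day 14 log2 fold changes reversed for Cpa1 (-0.147), Cela2a (-1.1), Try5 (-0.611), Cel (-1.3), Pnlip (-1.63), Prss2 (-1.73), Ctrb1 (-1.21), Try4 (-2.74), Mx2 (0.254), Car3 (0.401) and 1 further gene (0.306). The pseudocount alternative was not run, since the files hold counts, and quantile normalization was not run for the list tests. Depth set the level at which a gene could be tested.

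The replicate numbers are not known to pair the libraries. Over 15 pairs of groups the deviations of same-numbered libraries correlated between -0.236 and 0.325, over 0.1 in 5. The highest was that of days 4 and 6, in both of which replicate 1 has Xist and low Muc6. With the replicate block 388 genes were called at day 2, 1 at day 4, 1935 at day 6, 4540 at day 14, 137 for day 6 against day 2, 3319 for day 14 against day 6 and 4265 over any day. At day 1 edgeR called 0 (577 at an unadjusted p under 0.05; DESeq2 without the block 50). The list tests gave 118.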

Other observations

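Secretory cells of the epithelium were not part of the comparisons above except for Paneth cells at days 4 and 6. At day 14 Paneth cell markers fell in 8 of 18 members and rose in 2 (9 and 2 adjusted over the list alone, median log2 fold change -1.97; camera adjusted p = 1.36e-06; adjusted p = 0.48 with an estimated correlation). In log2 CPM minus the mean of uninfected tissue the median was -3.48 and -1.38 in replicates 1 and 2. Defa22 fell to 0.114 ± 0.076 CPM from 9.06 ± 0.313 and Defa21 to 0.213 ± 0.173 from 10.9 ± 0.115 (SD, n = 2 in each group). These are alpha-defensins whose near-identical copies make single values uncertain. Enteroendocrine markers, the hormone cells of the gut, fell at day 6 in 3 of 18 members (4 adjusted over the list alone, median -0.68; camera adjusted p = 0.00553; adjusted p = 0.563 with an estimated correlation), with medians in log2 CPM minus the mean of uninfected tissue of -0.867 and -0.427 in replicates 1 and 2. The granin gene Chga was at 39.4 ± 8.72 CPM against 80 ± 6.18 and Chgb at 144 ± 9.29 against 240 ± 3.94. Tuft cell markers, of the cells that sense worms, had a median of 0.91 at day 4 and 1.04 at day 14 (camera adjusted p = 8.14e-05 and 0.016; adjusted p = 0.59 and 0.723 with an estimated correlation). Of the members 1, the prostaglandin enzyme gene Hpgds, rose at day 14, and none adjusted over the list alone. Both list calls ended without 1 library, day 4 replicate 1 and day 14 replicate 2. Goblet cell markers rose in 5 of 18 members at day 14, 5 adjusted over the list alone, but the list did not pass (camera adjusted p = 0.0813). At day 1 goblet and Paneth cell markers were higher (camera adjusted p = 0.018 and 0.00422; adjusted p = 0.626 and 0.612 with an estimated correlation), with no member called over all genes and 1 and 0 adjusted over the list alone. Both calls ended without day 1 replicate 2, and the goblet cell call also without uninfected replicate 2.

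Among immune and stress lists, immediate early and heat shock genes rose in 4 of 15 members at day 14 (4 adjusted over the list alone, median 0.66; camera adjusted p = 0.0128; adjusted p = 0.612 with an estimated correlation). Egr1 was at 36.2 ± 2.07 CPM against 8.67 ± 3.75 and Fosb at 16.8 ± 2.6 against 2.37 ± 0.169. Without day 14 replicate 2 the list no longer passed, and without uninfected replicate 1 its median moved by more than 1.5 times. It was also higher at days 1, 2 and 6 (camera adjusted p = 1.14e-06, 0.0332 and 0.041; adjusted p = 0.47, 0.654 and 0.669 with an estimated correlation), with 0, 0 and 2 members called over all genes and 0, 0 and 2 adjusted over the list alone. The day 2 and day 6 calls ended without uninfected replicate 1 or without replicate 2 of that day. Type I interferon genes were higher at day 1 and lower at days 4 and 6 (camera adjusted p = 0.0121, 0.000171 and 0.0136; adjusted p = 0.723, 0.626 and 0.727 with an estimated correlation), with no member past the threshold over all genes or over the list alone. The day 1 direction turned without day 1 replicate 1 and its call ended without uninfected replicate 2, and the day 4 and day 6 calls ended without day 4 replicate 2 and uninfected replicate 1. T cell markers fell at day 6 in 2 of 19 members, 2 adjusted over the list alone (median -0.75; camera adjusted p = 0.00457; adjusted p = 0.653 with an estimated correlation). Cd4 was at 3.21 ± 0.488 CPM against 8.89 ± 0.677, and that call ended without day 6 replicate 1. At day 1 they were higher (median 0.30; camera adjusted p = 0.0123; adjusted p = 0.689 with an estimated correlation) with no member past either threshold, and not without day 1 replicate 1 or uninfected replicate 1. Plasma cell and immunoglobulin constant genes had medians of 0.57, 0.56 and 0.58 at days 1, 2 and 4 with no member called over all genes and 1, 1 and 1 adjusted over the list alone. Camera gave adjusted p = 4.75e-06, 0.015 and 0.00422, and adjusted p = 0.394, 0.563 and 0.508 with an estimated correlation. At day 6 this list was lower (median -0.54; camera adjusted p = 0.0332; adjusted p = 0.597 with an estimated correlation), 15 of 18 members lying below 0 and none past the threshold over all genes or over the list alone. Its medians in log2 CPM minus the mean of uninfected tissue were -1.02 and -0.153 in replicates 1 and 2, and the call ended without day 6 replicate 1. B cell markers had a median of 0.73 at day 4 (camera adjusted p = 0.00595; adjusted p = 0.489 with an estimated correlation), which no longer passed without day 4 replicate 1 or without uninfected replicate 1. Red blood cell genes had a median of -1.32 at day 6 (camera adjusted p = 0.0176; adjusted p = 0.537 with an estimated correlation). Hbb-bs fell to 1.76 ± 1.09 CPM from 5.83 ± 0.876; without uninfected replicate 1 the list no longer passed. Distal ileum markers had a median of -0.97 at day 14 (camera adjusted p = 0.0346; adjusted p = 0.496 with an estimated correlation), 3 of 6 falling and 1 rising (3 and 1 adjusted over the list alone). Mitochondrially encoded genes had a median of -0.76 (camera adjusted p = 0.015; adjusted p = 0.644 with an estimated correlation). Their share of counts was lowest in the libraries with batch tag 2, at 1.23% in day 2 replicate 2 and 1.26% and 1.78% at day 14. It was 2.08% to 2.8% in all other libraries, so that day 14 and the tag cannot be told apart here. At day 2 distal ileum markers were lower as well (camera adjusted p = 0.0425; adjusted p = 0.496 with an estimated correlation), with none called over all genes and 1 adjusted over the list alone, and not without day 2 replicate 1. The distal ileum median at day 14 was -1.54 and -1.11 in replicates 1 and 2, in log2 CPM minus the mean of uninfected tissue. Each day 14 call ended without day 14 replicate 1, and the mitochondrial call also without uninfected replicate 2.

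Markers of tissue next to the gut wall or in parts of it were tested as lists as well. The Brunner gland and stomach list had a median of -6.01 at day 14 with 1 of 11 members falling and 6 adjusted over the list alone (camera adjusted p = 0.0090; adjusted p = 0.60 with an estimated correlation), a call that ended without day 14 replicate 1. The exocrine pancreas list rose at day 14 in 14 of 19 members and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 8.27e-06; adjusted p = 0.563 with an estimated correlation). At days 1, 2 and 4 it was higher by camera (adjusted p = 4.33e-09, 1.63e-08 and 2.4e-11; adjusted p = 0.489, 0.489 and 0.471 with an estimated correlation), with no member called over all genes and 0, 16 and 16 adjusted over the list alone. The day 1 call ended without day 1 replicate 2, and those of days 2 and 14 with the batch tag as a term. Adipose markers were higher by camera at day 4 (adjusted p = 0.00090; adjusted p = 0.489 with an estimated correlation; median 1.34) with no member called over all genes or over the list alone. They were lower at day 14 (adjusted p = 0.0090; adjusted p = 0.563 with an estimated correlation), 3 of 10 falling and 4 adjusted over the list alone, and not without day 14 replicate 1. Eosinophil markers and circadian clock genes passed at no day, with the lowest camera adjusted p at 0.0587 and 0.256. In day 2 replicate 1 the clock genes Nr1d1 and Dbp stood at 15.7 and 2.24 CPM and Arntl at 46.6, against 134, 75.5 and 8.13 in replicate 2. Clock genes thus moved in opposite directions, and camera, which tests a list in 1 direction, cannot decide whether the clock differed. At day 14 Nr1d1 was at 56.13 and 72.74 CPM, against 147.5 and 161.7 in uninfected tissue. Dbp was at 9.849 and 19.59 CPM at day 14, against 58.96 and 65.97. In day 6 replicate 1 Dbp and Arntl were at 22.26 and 27.15 CPM, against 57.31 and 16.87 in replicate 2.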
